A study of Mus musculus with 4 samples.

How the data were processed

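RNA-seq libraries of engineered mouse neural tissue were compared between 2 groups, tissue stimulated with an electric field (EF) and unstimulated tissue (noEF), with 2 libraries per group. Groups and replicate numbers were taken from the sample titles, and the columns of the count table were matched to samples by the library names in the labels. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, fragmented, copied into cDNA from random hexamers, ligated to adapters, size selected and amplified by PCR. The protocol text describes no step that would keep the strand.

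The deposited table holds whole-number counts per gene for each library, not scaled, as its values show. Per the submitters' processing notes, which list tools without role or order, HISAT2 2.0.4, StringTie 2.2.1, DESeq2 1.44.0 and the GRCm38 genome build were used. The counting step, its annotation and its strand setting are not given in the sources used here. The table has 23874 genes, 22036 with an Ensembl identifier and 1838 gene models without one, which held 0.499% to 0.538% of the counts of a library, and 6556 genes had no count in any library. Counts of 1 were rarer than counts of 2 in each library (57 to 76 genes against 239 to 294), so the mates of a fragment may have been counted singly, and the counting error is then larger than the totals imply. PCR copies add to it. The intervals given here cover counting error only, and they may be too narrow because they treat each count as independent.

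Total counts ranged from 33748880 to 34554537 per library, which puts 1 count well below 0.1 CPM. The median tested gene had 21.2 CPM and the biological coefficient of variation was 0.161. Within each group a chi-square test of the counts gave 17.4 (EF) and 18.3 (noEF) times its degrees of freedom, so no library was a copy of its replicate.

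Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with the quasi-likelihood F test (robust dispersion and fit). P-values were adjusted by the Benjamini-Hochberg method over the 14263 genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are EF minus noEF, the standard error is the size of the log2 fold change divided by the square root of F, and CPM values use TMM-scaled library sizes. Where a group had 1 to 3 counts, the ratio of summed counts is given with an exact conditional binomial interval at 95%.

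The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The 30 lists hold 597 entries and 585 distinct genes, of which 584 were found in the table (3 through an older symbol) and 466 were tested. They cover neural stem cells and the cell cycle; immature and mature neurons, synapses, transmitters, ion channels, calcium, axon guidance and neurotrophic factors; immediate early genes; astrocytes and oligodendrocytes; Wnt and Notch pathways; matrix, vascular, fibroblast, microglial, ependymal and choroid plexus genes; and hypoxia, stress, interferon, cholesterol synthesis, mitochondrial and ribosomal genes. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 30 lists at 0.05. Beside it stand camera with an estimated correlation, fry, and the number of members called after adjustment over the list alone. With an estimated correlation, camera called 0 lists at an adjusted p under 0.05 and 1 list, the cell cycle, at an unadjusted p under 0.05. Camera with the preset correlation called 6 lists and fry called 1. The version with an estimated correlation also rests on the few residual degrees of freedom of 4 libraries, so it has little power. For the calcium list its correlation was -0.036, below the preset 0.01, yet the unadjusted camera p rose from 0.00522 to 0.0943. A call lost there does not by itself show that correlation between genes removes it. Named genes are the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 1 CPM, without predicted, unnamed or pseudogene models; the 4 members with the smallest p in each list; and Nes, Sox2, Mki67, Dcx, Tubb3, Map2, Rbfox3, Syn1, Gfap, Olig2, Mbp, Bdnf and Fos. Other list members named in the text were added after their values were seen.

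Gene coordinates, exon lengths and GC content came from GENCODE M21 on GRCm38, which held 22022 of the identifiers. Exon overlaps of at least 1 base between genes of the table were found with bedtools 2.31.1. Positions of the gene models without an Ensembl identifier were not used here.

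The alternatives set before the data were examined were DESeq2's size factors (RLE) or library totals in place of TMM, no filter or a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a fit without the robust option, an adjusted p under 0.01, a log2 fold change of at least 1, and the other list tests. After seeing the data, 3 more were added: a loess trend on exon length and GC content removed from each library (its lists tested with the preset and with an estimated correlation), overlapping genes left out, and mitochondrially encoded genes left out. The procedure was tested on simulated counts with the means, totals and dispersions of EF against noEF and 200 changed genes among 14023 tested. It recovered 42% of genes changed 1.5-fold, 76% changed 2-fold, 94% changed 4-fold and 100% changed 8-fold, called 8 of 13803 unchanged genes, and called the shifted list and 0 others. A small change in a single gene is thus often missed with 2 libraries per group. The simulated genes were drawn independently of each other from the dispersion trend, without a length trend between libraries. The few false calls of genes and lists there therefore say little about false calls in the real libraries.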

Results

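Gene expression was measured by RNA sequencing in engineered neural tissue of the mouse, a gel culture made from neural stem cells. Neurospheres, which are free-floating clusters of neural stem and progenitor cells, were embedded in Matrigel, a basement membrane extract. Their medium held 20 ng/ml basic fibroblast growth factor, a mitogen of neural progenitors. The EF group received an electric field of 150 mV/mm for 30 min a day on 3 days and was then kept for another 7 days, while the noEF group was left unstimulated. The sample labels give both groups as engineered tissue, but the series design names suspensions of neural stem cells as the control, so what noEF was rests on the sample labels. 2 libraries per group were analysed here, although the labels state 3 replicates per group. Total counts per library were 34554537 in EF 1, 33972252 in EF 2, 33748880 in noEF 1 and 34458072 in noEF 2, and between 15548 and 15723 genes had at least 1 count in a library. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Across the tested genes, Spearman's rho of log2 counts scaled to library size (CPM) was 0.991 between the EF libraries and 0.990 between the noEF libraries. Between libraries of different groups it was 0.978 to 0.988, and genes are not independent replicates. The first principal component held 43.5% of the variance and placed the EF libraries at -29.7 and -13.6 and the noEF libraries at 23.8 and 19.4. The second held 32.3% and set noEF 1 at 22.2 and noEF 2 at -28.3, so the distance between the noEF replicates was large compared with that between the groups.

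The comparison of EF with noEF asks which transcripts differ in neural tissue 7 days after electrical stimulation ended. Of 20 cell cycle genes 17 were higher in EF, among them Top2a at 2.04-fold and Rrm2 at 1.87-fold. Gfap, the intermediate filament of astrocytes, was 2.74-fold lower in EF. With it, 7 of 20 astrocyte genes and 8 of 20 cholesterol synthesis genes were lower. Of 13 mitochondrially encoded genes 8 were lower, but all 8 lost their call once the length and GC trend of each library was removed (list median 0.07, camera adjusted p = 0.992). Of the glutamate receptor genes, Gria2, Grm5, Grm3 and Gria1 were higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 546 of 14263 tested genes were higher in EF and 712 were lower. Of these, 68 and 79 differed at least 2-fold. Higher genes made up 43.4% of the calls, but with library totals in place of TMM scaling they made up 69.3%, with 1138 genes higher and 505 lower. Without EF 1 the counts fell to 217 higher and 337 lower genes, of which 196 and 300 were among the calls from all 4 libraries.

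Cell division genes showed the most uniform difference among the 30 gene lists. Of 20 genes in the cell cycle list, 17 were higher in EF, 0 were lower and 3 (Birc5, Tyms and Ccne2) did not pass the test. When adjusted over the list alone, 19 were higher. Top2a, the topoisomerase that untangles DNA in dividing cells (ENSMUSG00000020914, GRCm38 chromosome 11, 98992943 to 99024189), reached 203 ± 29.6 CPM in EF and 99.4 ± 3.27 CPM in noEF (SD, n = 2 each), a log2 fold change of 1.03 (SE 0.10) with an edgeR adjusted p of 5.01e-05. Rrm2, a subunit of ribonucleotide reductase (ENSMUSG00000020649, chromosome 12, 24708241 to 24714146), rose from 86.7 ± 3.89 to 162 ± 2.82 CPM (SD, n = 2 each), and its log2 fold change of 0.90 (SE 0.09) had an edgeR adjusted p of 2.71e-05. The mitotic cyclin Ccnb1 rose by 0.79, the replicative helicase subunit Mcm6 by 0.84 and the proliferation marker Mki67 by 0.69 on the log2 scale, with edgeR adjusted p-values of 1.05e-04, 1.05e-04 and 0.0021. Ncapg2, a subunit of the condensin complex of mitotic chromosomes, was among the 10 genes with the largest rises, at a log2 fold change of 1.79 (SE 0.32, edgeR adjusted p = 0.00469). The list's median log2 fold change was 0.70, and limma's camera test with a preset correlation called it higher (adjusted p = 4.11e-13). With an estimated correlation the list gave adjusted p = 0.618, and across its 18 alternatives the adjusted p ran from 1.58e-35 to 0.669. The rotation test fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, also called it (adjusted p = 0.0363).

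**Figure D1:**
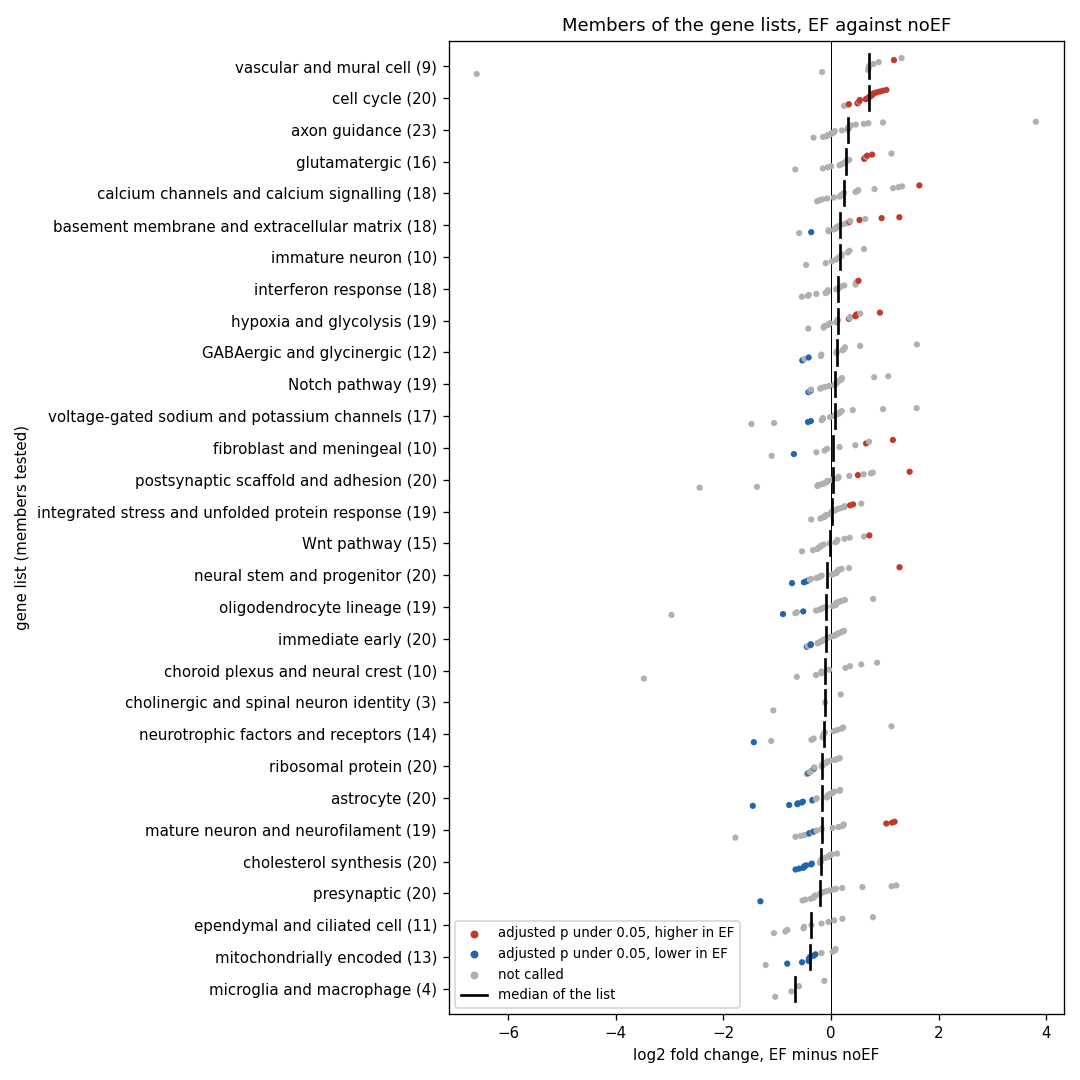
Log2 fold change of EF minus noEF (horizontal axis) for each tested member of the 30 gene lists (vertical axis), from edgeR with 2 libraries per group. Members called higher (red), called lower (blue) or not called (grey) and list medians (black ticks) are shown, with 17 red points in the cell cycle list and 7 blue points in the astrocyte list.

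Astrocyte genes were lower in part. In the astrocyte list 7 of 20 genes were lower in EF and 0 were higher, and 9 were lower when adjusted over the list alone. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912) fell from 656 ± 21.3 to 239 ± 2.52 CPM (SD, n = 2 each), a log2 fold change of -1.45 (SE 0.08, edgeR adjusted p = 1.06e-07). The secreted chaperone Clu was at -0.78, the lipid carrier Apoe at -0.63 and the gap junction protein gene Gja1 at -0.62 on the log2 scale, with edgeR adjusted p-values of 4.49e-05, 2.63e-04 and 2.78e-04. Aldoc, Aqp4 and Atp1b2 were the other lower genes, at -0.54, -0.52 and -0.34. The glutamate transporter genes Slc1a3 and Slc1a2, the glutamine synthetase gene Glul and Aldh1l1, all known astrocyte genes, did not pass the test and had log2 fold changes of 0.16, -0.08, 0.06 and 0.03. The list's median was -0.17 and camera called it lower (adjusted p = 0.00559), with adjusted p = 0.621 with an estimated correlation. Fry (adjusted p = 0.0599) and the fit without EF 2 (adjusted p = 0.0521) did not call it, within a range of 3.94e-14 to 0.669 over its 18 alternatives.

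Among 20 neural stem and progenitor genes, Tnc was higher and Hopx, Fabp7, Sox1 and Sox9 were lower, against 2 higher and 6 lower when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.436). Tnc, which encodes the matrix protein tenascin C, rose 2.42-fold to 98.6 ± 4.61 CPM (SD, n = 2; edgeR adjusted p = 3.47e-06). Fabp7, a fatty acid binding protein of radial glia, fell from 3355 ± 280 to 2365 ± 118 CPM (SD, n = 2 each; edgeR adjusted p = 0.00195). With the length and GC trend of each library removed, its log2 fold change went from -0.50 to -0.23 (edgeR adjusted p = 0.0456). It kept its call there, as did the other called genes of the list. Nes and Sox2, general markers of neural progenitors, had log2 fold changes of 0.14 and -0.27 and did not pass (edgeR adjusted p = 0.369 and 0.0597). Of 19 oligodendrocyte lineage genes, Gpr17 and the progenitor receptor Pdgfra were lower (-0.89 and -0.52; edgeR adjusted p = 0.0164 and 0.0396) and 0 were higher, with the same 2 when adjusted over the list alone. Olig2 at 0.09 and the myelin gene Mbp at 0.20 did not pass, and the list was not called (camera adjusted p = 0.444). Exons of Gpr17 overlap Lims2 on the opposite strand. None of the 11 ependymal and ciliated cell genes, the 10 choroid plexus and neural crest genes or the 4 microglia and macrophage genes tested passed in edgeR. At an adjusted p over the list alone 2 microglia and macrophage genes were lower and 0 genes of the other lists passed, and camera gave adjusted p-values of 0.105, 0.840 and 0.0623.

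**Figure D2:**
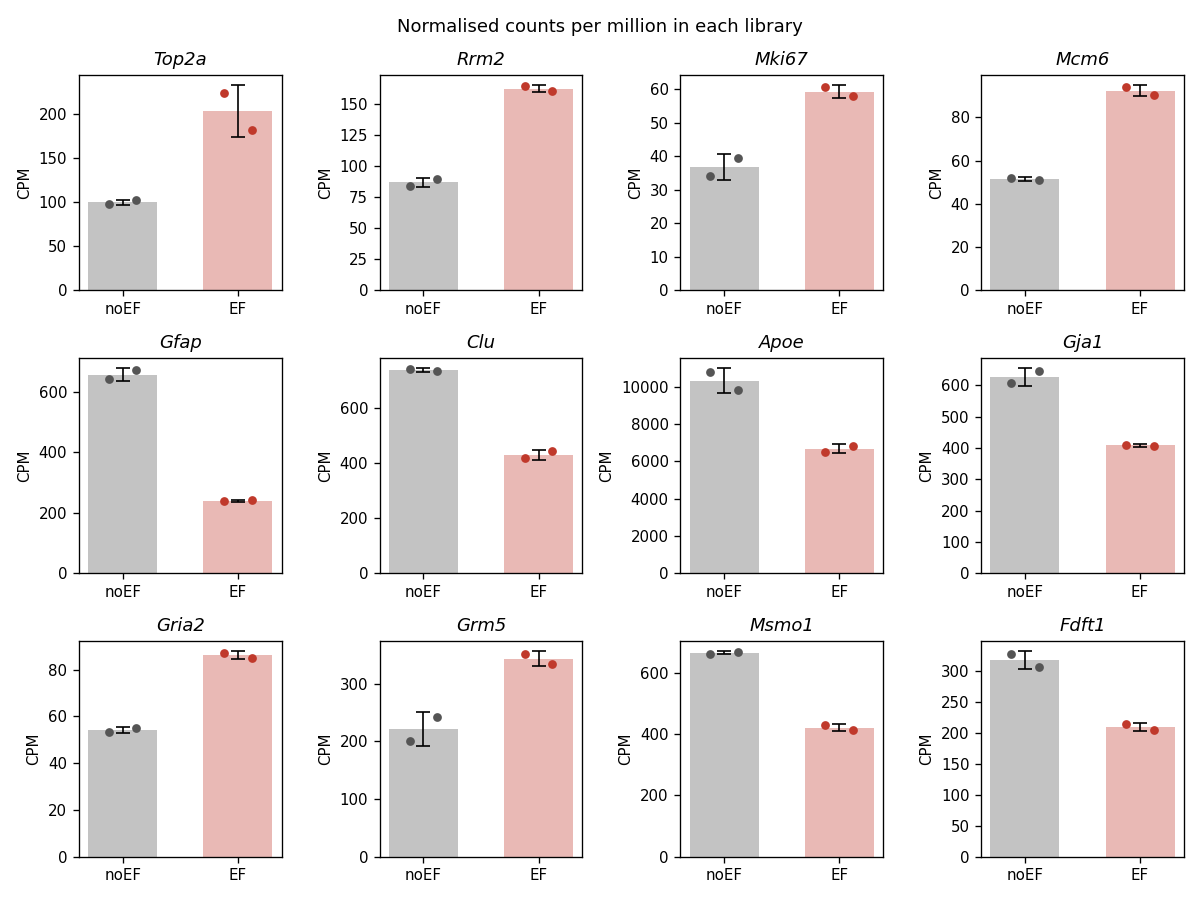
TMM-normalised CPM (vertical axes, starting at 0) of 12 named genes in noEF and EF. Points are the 2 libraries of each group, bars their mean and error bars the SD: Top2a lies near 99.4 CPM in noEF and 203 CPM in EF, and Gfap near 656 and 239 CPM.

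Genes of the neuronal lists moved in both directions. Bulk counts do not show which cells carried these differences. Of the genes that mark neurons, Tubb3, Rbfox3 and Syn1 had a mean of 11.6, 1.35 and 12.2 CPM over all libraries, and Map2 480 CPM. Gria2 and Gria1, which encode AMPA receptor subunits, rose by 0.67 and 0.62 on the log2 scale, and the metabotropic receptor genes Grm3 and Grm5 rose by 0.76 and 0.63 (edgeR adjusted p = 6.64e-04, 0.0111, 0.00287 and 0.00117). Grm5 was the most abundant of these, at 343 ± 12.9 CPM in EF and 222 ± 29.5 CPM in noEF (SD, n = 2 each). They were the 4 called members of 16 in the glutamatergic list, 5 when adjusted over the list alone, and 0 members were lower. Camera called this list higher (adjusted p = 0.00806), with adjusted p = 0.621 with an estimated correlation. It lost that call without EF 1 (adjusted p = 0.157), without noEF 2 (adjusted p = 0.101), by fry (adjusted p = 0.134) and with the length and GC trend of each library removed (adjusted p = 0.0513), in a range of 0.00265 to 0.669 over its 18 alternatives. The list of 18 calcium channel and calcium signalling genes was also called higher (camera adjusted p = 0.0261; adjusted p = 0.621 with an estimated correlation). Its single called member was Calb2, the calcium buffer calretinin, at 3.96 ± 0.577 against 1.27 ± 0.0561 CPM (SD, n = 2 each; edgeR adjusted p = 0.0158). That list had 2 higher members when adjusted over the list alone, and 10 of its 18 alternatives kept the call, with adjusted p-values from 0.0137 to 0.669. With the length and GC trend of each library removed, its median went from 0.23 to 0.12 and camera no longer called it (adjusted p = 0.142).

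Both GABA-B receptor genes, Gabbr1 and Gabbr2, were lower (-0.42 and -0.53; edgeR adjusted p = 0.00639 and 0.0438), and they were the 2 called members of 12 GABAergic and glycinergic genes. When adjusted over the list alone, 3 were lower. The median of this list was 0.10 while camera's direction was down, far from the threshold (adjusted p = 0.997). Of 19 mature neuron and neurofilament genes, Scg2, Camk2a and Nrgn were higher by 1.18, 1.13 and 1.03 and Mapt and Rtn1 were lower (-0.40 and -0.33). When adjusted over the list alone, 4 were higher and 6 lower (camera adjusted p = 0.579). Scg2 encodes a secretory granule protein, Camk2a a calcium-dependent kinase of synapses and Nrgn the calmodulin-binding protein neurogranin, and each stayed below 15 CPM on average. The pentraxin genes Nptx2 and Nptx1, whose products cluster AMPA receptors, rose by 1.46 and 0.50 (edgeR adjusted p = 3.54e-04 and 0.00163). They were the 2 called members of 20 postsynaptic scaffold and adhesion genes, also when adjusted over the list alone (camera adjusted p = 0.609). Of 20 presynaptic genes Nrxn3 was lower (-1.31, edgeR adjusted p = 0.0497) and 0 were higher. When adjusted over the list alone, 1 was higher and 4 lower (camera adjusted p = 0.135). Nrxn3 kept its call in 5 of its 15 alternatives. With the length and GC trend of each library removed, 1 presynaptic gene was higher and 4 were lower, Nrxn3 among them (camera adjusted p = 0.142). None of the 10 immature neuron genes or the 3 cholinergic and spinal neuron genes tested passed, over all genes or over the list alone (camera adjusted p = 0.347 and 0.820). Dcx, a microtubule protein of migrating young neurons, was at -0.46 with an edgeR adjusted p of 0.109. Tubb3, Map2, Rbfox3 and Syn1, which mark neurons, were at 0.19, 0.20, -0.18 and -0.19 and did not pass. With the length and GC trend of each library removed, 2 immature neuron genes were called. Dcx was lower (-0.61, edgeR adjusted p = 0.0215) and Gap43 higher (0.33, edgeR adjusted p = 0.0135).

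Kcnj10, the inward rectifier of glia, was lower (-0.43; edgeR adjusted p = 0.0298). Of the 17 voltage-gated sodium and potassium channel genes in its list 2 were lower and 0 higher, also over the list alone (camera adjusted p = 0.840). Ntn1, the guidance cue netrin 1, was the single called gene of 23 in the axon guidance list, at 171 ± 7.37 against 136 ± 0.514 CPM (SD, n = 2 each; edgeR adjusted p = 0.0264; camera adjusted p = 0.0623; 1 higher when adjusted over the list alone). Of 14 neurotrophic factor and receptor genes Cntf was lower (-1.43), and its exons overlap those of Zfp91 on the same strand. Bdnf was at -0.13 and did not pass, and the list was not called (camera adjusted p = 0.430; 1 lower when adjusted over the list alone). Among 20 immediate early genes, which respond within minutes to activity and growth factors, Fosl2, Junb and Nr4a2 were lower (-0.45, -0.38 and -0.38; edgeR adjusted p = 0.00515, 0.0163 and 0.0314), and 5 were lower when adjusted over the list alone. Fos itself, at 948 ± 26.0 against 1113 ± 33.7 CPM (SD, n = 2 each), did not pass (edgeR adjusted p = 0.0798), and the list was not called (camera adjusted p = 0.233). Junb overlaps Prdx2 on the opposite strand.

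Cholesterol synthesis genes were lower in part. In that list 8 of 20 genes were lower in EF and 0 higher, the same counts as when adjusted over the list alone, and 18 of 20 had a log2 fold change below 0. Msmo1, a sterol methyl oxidase (ENSMUSG00000031604, chromosome 8, 64718139 to 64733792), fell from 666 ± 4.93 to 422 ± 11.1 CPM (SD, n = 2 each), a log2 fold change of -0.66 (SE 0.08, edgeR adjusted p = 1.52e-04). The squalene synthase gene Fdft1 was at -0.60, the farnesyl diphosphate synthase gene Fdps at -0.52 and Nsdhl at -0.49 (edgeR adjusted p = 5.06e-04, 0.00222 and 0.0041). Fdft1 overlaps Ctsb on the opposite strand and Fdps overlaps Gm43738 on the same strand. Camera called the list lower (adjusted p = 4.63e-04), with adjusted p = 0.621 with an estimated correlation and 0.0631 by fry, in a range of 5.69e-10 to 0.669 over its 18 alternatives.

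Mitochondrially encoded transcripts were lower in 8 of 13 genes and higher in 0, also over the list alone, with a median log2 fold change of -0.39 (camera adjusted p = 9.72e-04; adjusted p = 0.621 with an estimated correlation and 0.167 by fry). Mt-Nd6 was lowest among the called genes, at 1674 ± 44.0 against 2943 ± 36.1 CPM (SD, n = 2 each). It overlaps mt-Nd5 on the other strand, and reads from the stretch they share cannot be assigned to either gene unless counting used strand. The most abundant, mt-Co1, had a log2 fold change of 0.08 and did not pass. Mitochondrial genes took 9.42% and 8.47% of the counts in EF and 9.27% and 10.1% in noEF, ranges that overlap. With the length and GC trend of each library removed, all 8 genes lost their call by edgeR's quasi-likelihood test, with mt-Nd6 going from -0.81 (SE 0.08) to -0.27 (SE 0.11), and mt-Nd3, not called before, was lower. The list's median was then 0.07 and its camera adjusted p was 0.992, in a range of 1.29e-14 to 0.997 over the 17 alternatives. Of 20 ribosomal protein genes Rps24 and Rps2 were lower (-0.42 and -0.31; edgeR adjusted p = 0.0309 and 0.0402), 3 when adjusted over the list alone (camera adjusted p = 0.0623). These genes have many processed copies in the genome that can share reads with them. With the trend removed Rps24 was at -0.54 (SE 0.14) and Rps2 at -0.12 (SE 0.07) and both missed the threshold (edgeR adjusted p = 0.0897 and 0.293), Rps24 with a larger fall and a larger SE, while Rpl4, Rpl3 and Rps6 were called higher.

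Of 19 hypoxia and glycolysis genes 5 were higher and 0 lower, against 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0623). Egln3, an oxygen-sensing prolyl hydroxylase, rose from 14.7 ± 2.22 to 27.6 ± 2.62 CPM (SD, n = 2 each; edgeR adjusted p = 0.00255). The collagen prolyl hydroxylase gene P4ha1 and the lactate dehydrogenase gene Ldha rose by 0.47 and 0.33 on the log2 scale, with Pfkl and Pdk1 the others. Of 19 genes of the integrated stress and unfolded protein response Hspa5 and Mthfd2 were higher (0.35 and 0.41; edgeR adjusted p = 0.0177 and 0.0449), the same count when adjusted over the list alone (camera adjusted p = 0.559). With the length and GC trend removed camera called both lists higher (adjusted p = 0.01005 and 0.0399), with adjusted p = 0.669 with an estimated correlation for each in that fit, and 0.621 and 0.725 without the removal. The interferon response list held 1 higher gene of 18, Gbp3 (0.51; edgeR adjusted p = 0.0313; camera adjusted p = 0.820), also over the list alone.

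Among 18 basement membrane and extracellular matrix genes, the laminin genes Lama4, Lamb1 and Lamc1 and the fibronectin gene Fn1 were higher (1.27, 0.94, 0.34 and 0.53) and Sparc was lower (-0.37). When adjusted over the list alone, 6 were higher and 2 lower (camera adjusted p = 0.0623). Lamb1 reached 14.9 ± 0.923 against 7.75 ± 1.36 CPM (SD, n = 2 each; edgeR adjusted p = 0.00737). Of 9 vascular and mural cell genes Acta2, smooth muscle actin, was higher (6.76 ± 2.72 against 3.01 ± 0.177 CPM, SD, n = 2 each; edgeR adjusted p = 0.0309), also over the list alone. Acta2 stood at 8.68 CPM in EF 1 and 4.84 CPM in EF 2. Leaving out each library in turn moved its log2 fold change from 1.17 to between 0.69 and 1.53. The median of that list was 0.70, its mean was -0.06 because Pdgfrb had 0 counts in EF and 23 in noEF, and it was not called (camera adjusted p = 0.164). Of 10 fibroblast and meningeal genes Ogn and Fbln1 were higher (1.15 and 0.65) and Ptgds lower (-0.69; edgeR adjusted p = 5.08e-04), with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.820). Axin2, a feedback target of Wnt signalling, was higher (0.71; edgeR adjusted p = 0.0257) as the single called gene of 15 in the Wnt list, and Hey1 and Hes6 were the 2 lower genes of 19 in the Notch list (-0.42 and -0.37; edgeR adjusted p = 0.0327 and 0.0431). Both counts were the same over the list alone, and neither list was called (camera adjusted p = 0.932 and 0.856). With the length and GC trend of each library removed, Axin2 and 1 of the 2 Notch genes kept their call.

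The largest fold changes belonged in part to overlapping gene models. Akap11, an anchoring protein for protein kinase A (ENSMUSG00000022016, chromosome 14, 78492246 to 78536808), had 2747 and 2825 counts in EF and 341 and 367 in noEF, a 7.38-fold rise with a log2 fold change of 2.88 (SE 0.12, edgeR adjusted p = 4.29e-09). No annotated gene of the table overlaps its exons. No single gene model without an Ensembl identifier lost more than 2263 counts, against the gain of 4864 counts in Akap11. Whether several such models together lost as many to it was not checked. Loxl2, a lysyl oxidase that crosslinks collagen, rose by 2.94 (SE 0.54) and Plau, the urokinase-type plasminogen activator, by 1.80 (SE 0.28) on the log2 scale (edgeR adjusted p = 0.00408 and 0.00128). Loxl2 had 7 and 25 counts in noEF, and leaving out each library in turn gave log2 fold changes of 2.32 to 4.08. Fxyd1, a regulator of the sodium pump, fell by 2.14 (SE 0.18) from 38.1 ± 3.49 to 8.66 ± 2.38 CPM (SD, n = 2 each; edgeR adjusted p = 2.83e-05). The other genes with the largest rises were Rab43, Ap4b1, Tmem144, Cyb5d1, Hs3st2, Ncapg2 and Tnfsf18, and those with the largest falls were Lrch4, Gp1bb, Pcdhga1, Ccdc148, Meig1, Tomt, Rasgef1c, Sap25 and Slc14a1. Cyb5d1 overlaps Naa38 and Tomt overlaps Anapc15 on the opposite strand.

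Rab43 (ENSMUSG00000030055, chromosome 6, 87788853 to 87812164) had 409 and 442 counts in EF and 0 and 2 in noEF, a ratio of 399. The 95% exact interval for counting error was 110 to 3299, which is too narrow if mates were counted singly. Gm45140, which shares exons with it on the same strand, had 5 and 0 counts in EF and 476 and 508 in noEF, and the sum of both genes differed by -0.30 on the log2 scale. Lrch4 had 3 counts in EF and 228 in noEF, 81.1-fold lower (95% exact interval 27.4 to 396), but its sum with Gm20605 differed by 0.28. The sums for Ap4b1 with Gm43064 and for Sap25 with Gm20605 differed by -0.16 and 0.46. Had the partners of Rab43, Lrch4, Ap4b1 and Sap25 kept their noEF level, the sums would have differed by 0.85, -0.99, 0.77 and -0.65, so the values of these 4 genes taken alone are uncertain. Gp1bb shares exons with Gm49601 and Sept5, and Pcdhga1 with the protocadherin gamma cluster. These partners hold most of the counts, and the sums (-0.06 and 0.04) would have been near 0 in either case (-0.11 and -0.04), so they do not tell whether reads moved.

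**Figure D3:**
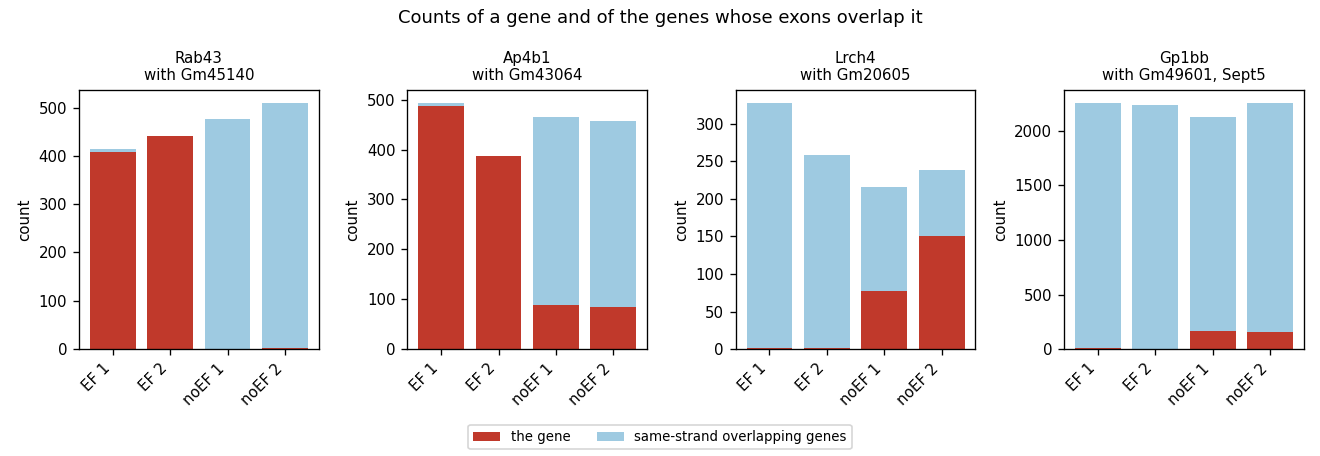
Counts per library (vertical axes, starting at 0) of Rab43, Ap4b1, Lrch4 and Gp1bb (red) stacked on those of the genes whose exons overlap them on the same strand (blue). The red part differs between EF and noEF, while the summed counts differ by -0.30, -0.16, 0.28 and -0.06 on the log2 scale, the last in a locus where the partners hold most of the counts.

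Fold changes followed exon length. Among annotated genes with a mean of at least 1 CPM, divided into 5 classes of about equal size by exon length, the median log2 fold change was -0.20 in the class with the shortest exons (up to 2646 bases) and 0.09 in that with the longest. The class with the shortest exons held 316 of the lower and 51 of the higher genes. The difference between replicates followed exon length as well, with a Spearman's rho across 12257 genes of 0.228 for EF 1 minus EF 2 and -0.330 for noEF 1 minus noEF 2, against 0.114 to 0.389 for EF minus noEF pairs. With the trend on length and GC content removed from each library, 636 genes were higher and 867 lower, and 431 and 554 of them were among the original calls. The cell cycle, astrocyte and cholesterol synthesis lists then had 16 higher, 8 lower and 10 lower genes, and camera called each of them (adjusted p = 1.26e-13, 0.01005 and 2.67e-05). Each of these calls was lost in that fit with an estimated correlation (camera adjusted p = 0.669), a test with little power at 2 libraries per group.

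**Figure D4:**
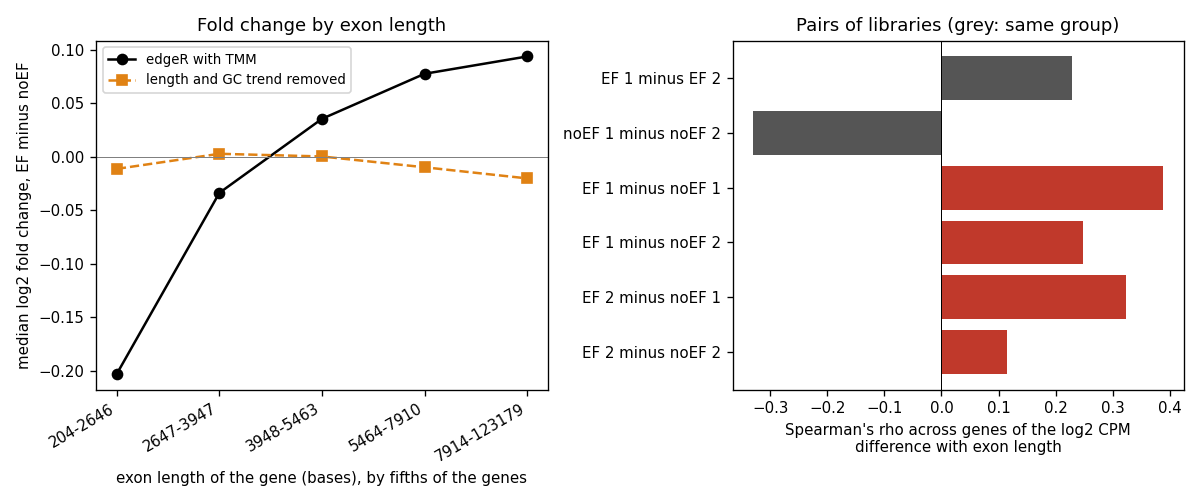
Left, median log2 fold change of EF minus noEF (vertical axis) in 5 classes of genes by exon length in bases (horizontal axis), from edgeR with TMM (black) and with the length and GC trend removed (orange). Right, Spearman's rho across 12257 genes between exon length and the log2 CPM difference of each pair of libraries, with pairs of the same group in grey (0.228 and -0.330) and pairs of different groups in red (0.114 to 0.389).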

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

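The removal of the length and GC trend (also with an estimated correlation) and the fits without overlapping or mitochondrially encoded genes were added after seeing the data. Of 546 higher and 712 lower genes, no call changed sign in any other fit except 14 with the trend removed. Counts moved by over 1.5 times with library totals only (1138 higher), without a filter (915 higher, 1203 lower), without the robust option (337 higher), at an adjusted p under 0.01 (173 and 273) and at a log2 fold change of at least 1 (68 and 79), where fewer calls follow from the stricter limit; for the others the cause was not tested. Leaving out each library in turn, with a lone library assumed to vary like the other group, gave 217 to 790 higher and 337 to 1065 lower genes; the lowest counts came without EF 1 and the highest without noEF 2. The 3 higher and 3 lower lists became 7 and 5 without a filter, 5 and 5 with at least 1 CPM in 2 libraries, 5 higher by DESeq2, 5 higher by limma-voom, 0 and 0 by camera with an estimated correlation, with or without the trend removed (1 list at an unadjusted p under 0.05 in each), and 1 and 0 by fry. Leaving out a library gave 3 to 5 higher and 3 to 5 lower lists. The cause of these moves was not tested.

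With the replicate number as a block, 410 genes were higher, 568 lower and 5 lists higher. The replicate numbers come from the sample titles and are not stated to mark a shared batch. For an EF library the number in the submitters' library name differs from that in its title. That library and its noEF partner in the block thus share a number in the titles only. The deviations of libraries with the same title number from their group means had a correlation of -0.09 across genes. This value shows no common shift of these pairs, but the pairing is uncertain, so it cannot tell whether libraries shared a batch.

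Of 149 named genes, 84 were called, and 40 of these kept their direction and call under each refit that gave a value; the stricter limits on adjusted p and fold change are not counted there. Mt-Co2 changed sign with the trend removed, to a log2 fold change of 0.14 (edgeR adjusted p = 0.675); its exons are short and the correction moves short genes upward. At this depth and with 2 libraries per group, 42% of simulated 1.5-fold changes were called, so genes not called may still differ by that much.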

Other observations

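The tests of the largest changes against other genes and of length trends between replicates were chosen after the result was seen, as were the genes named in the next paragraph.

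Several genes outside the lists and the rule for named genes had small p-values, and no test of a shared function was made on them. Fbln2, the matrix protein fibulin 2, stood at 194 ± 4.36 against 89.9 ± 0.779 CPM (SD, n = 2 each; edgeR adjusted p = 3.13e-06), Nell2 rose 2.04-fold, the apelin gene Apln 2.24-fold and Igfbp4, which binds insulin-like growth factors, 1.77-fold. Txnip, a glucose-responsive inhibitor of thioredoxin, rose 2.00-fold. Hells, a chromatin helicase, rose 2.36-fold, Pclaf 1.92-fold, Prc1, a protein of the mitotic spindle, 1.78-fold and the replicative helicase subunit Mcm4 1.67-fold. Among the lower genes, Gpr37l1, a receptor found on astrocytes, was 2.98-fold lower (edgeR adjusted p = 3.09e-07), Padi2 3.37-fold, Cldn10 2.34-fold and Cacng5 2.19-fold lower. The lipid desaturase gene Scd1 was 1.67-fold lower, the glutathione transferase gene Gstm1 1.66-fold and the ferritin gene Fth1 1.97-fold lower. Gstm1 and Fth1 have close copies elsewhere in the genome, so their counts are uncertain.

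Called genes (edgeR adjusted p under 0.05) with an absolute log2 fold change of at least 2 and a mean of at least 1 CPM numbered 18. Of these, 10 (55.6%) have exons overlapping another gene of the table on the same strand, against 4.53% of the other tested genes (Fisher's exact test, two-sided, p = 1.24e-09). That p-value is likely too small, since the test counts partners of each other as independent (Rab43 with Gm45140, Ap4b1 with Gm43064). The other tested genes also had no limit on mean CPM. A different division of reads between overlapping models may contribute to these 10, and if genes were assembled or assigned separately in each group, which the sources used here do not say, that step would be confounded with stimulation. A change of the locus as a whole is argued against, since the summed counts of each gene and its partners had a median absolute log2 ratio of 0.13 and a maximum of 0.30. A switch between transcripts that share these exons stays open. So does a change of the gene alone where the partners hold most of the counts, as for Gp1bb, Pcdhga1, Gm20521, Gm49395 and Gm43302. The sums for Gm20521, Gm49395 and Gm43302 differed by -0.04, 0.11 and 0.27. Had their partners kept their noEF level, these would have been 0.09, -0.085 and 0.37, so the sums do not tell whether reads moved there. Akap11, Loxl2, Fxyd1, Meig1, Ccdc148 and Gm10273 have no annotated partner in the table on either strand, while Tomt has one on the opposite strand and NewGene_567 could not be checked.

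Of 5 classes of genes by exon length, the one with the shortest exons held 45.1% of the lower calls. A length trend between libraries that is unrelated to stimulation is a candidate explanation, because the log ratio of replicates followed exon length as strongly (mean absolute Spearman's rho 0.279 across genes) as that of libraries from different groups (0.268). The mitochondrially encoded genes have exons of 204 to 1824 bases, and the list lost its call with the trend removed, the median going from -0.39 to 0.07. Their fall may therefore reflect RNA integrity or size selection, which were not tested, and a biological fall is not excluded.

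Cell cycle genes were higher and part of the astrocyte genes lower in EF. For the cell cycle list, a single library is argued against by medians of 0.63 to 0.74 when each was left out in turn. With the length and GC trend removed, that list had a median log2 fold change of 0.66 with 16 called genes. In the astrocyte list 7 of the 7 lower genes kept their call. Neither outcome was in much doubt, so the removal adds little. The lists' median exon lengths, 4150 and 3844.5 bases, fall in classes with median log2 fold changes of only 0.04 and -0.03. The small size of the trend at these lengths argues against it as the source. Both list calls were lost with an estimated correlation (camera adjusted p = 0.618 and 0.621), a test with little power at 2 libraries per group. A different share of dividing or astrocyte-like cells, a change of expression within cells and a difference between individual cultures unrelated to stimulation stay open, since bulk counts from 2 libraries per group do not separate them.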
